A study of Mus musculus with 15 samples.

How the data were processed

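Bulk RNA sequencing of mouse stomach tissue was analyzed from 15 libraries in 5 groups of 3: normal tissue and tumors of the antrum, greater curvature, lesser curvature and corpus. Groups and replicate numbers were taken from the sample labels. The group line of the count table gives antrum and corpus separate codes, as the labels do, while that of the other deposited table codes both as T1, for a reason not given in the sources used here. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.19, and kallisto 0.44.0, sleuth, DESeq2 and the GRCm38.p6 genome are named, without the role or order of each. The deposited count table holds estimated counts per gene, given as whole numbers for 36144 genes, as the authors made it with the tools named above. The other deposited table is named for FPKM, but each of its columns adds up to 1e+06, so it was read as TPM (transcript abundances scaled to a fixed total) made by the authors from the same samples. The design had assumed FPKM. How transcripts were summed to genes, which annotation was used and whether the Myc transgene was in the reference are not given in the sources used here.

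Genes were used by the symbol in the tables. Of the symbols, 99.3% are in GENCODE M21, from which coordinates on GRCm38 were taken, and 26 symbols had been turned into dates, 2 of them in more than 1 entry. In 1747 entries the count was 0 and the TPM above 0. Library totals ran from 7957165 to 21564972 counts, so 1 count stands for 0.0477 to 0.112 CPM (counts per 1e+06 of the scaled library), and a group at 0 was bounded with a floor of 3 counts over the group, with all normals and with each left out. These floors cover counting error only.

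Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and 1 quasi-likelihood model with robust dispersions held all 15 samples by group. The comparisons were all tumors against normal, each site against normal, each site against the other 3 sites, the greater against the lesser curvature, and an F test among the 4 sites. Fold changes are log2, adjusted p-values are by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. An adjusted p given for a gene without a tool is from edgeR, and SE is the standard error of its log2 fold change. CPM values use the scaled library sizes, and log2 CPM a prior count of 2.

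The 33 gene lists, 433 members in all of which 2 are absent from the tables, were written before the data were examined, as were the groups, tests and other settings to try. They cover neuroendocrine markers, enteroendocrine hormones, tuft cells, Myc targets, DNA replication, mitosis, p53 targets, CXCR2 ligands and receptors, neutrophils, macrophages and monocytes, T and NK cells, B and plasma cells, mast cells, parietal cells, chief cells, pit and neck mucous cells, intestinal epithelium, pan-epithelial markers, squamous epithelium, antral glands, smooth muscle, fibroblasts and matrix, endothelium, enteric neurons and glia, pancreatic acinar cells, adipocytes, erythroid cells, interferon response, antigen presentation, glycolysis and hypoxia, mesenchymal transition, immediate early genes and mitochondrially encoded genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjusted p-values of lists are over the lists of a comparison. Members were counted by their adjusted p over all genes and by one adjusted over the list alone.

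Genes were named by a rule. Whatever their values, it names genes that include Pou2f3, Rb1, Trp53, Myc, Cxcl5, Cxcr2, Neurod1, Chga, Syp and Dclk1. For all tumors against normal it adds the 10 largest changes in each direction among called genes with all 12 tumors beyond all normals and a mean of at least 10 CPM on the higher side. For each site against normal, and between sites, it adds 5 in each direction, and from each list up to 4 tested members with the smallest p. Predicted genes, pseudogenes, antibody and T cell receptor segments and genes without a symbol were passed over. Genes outside the rule are said to be picked after their values were seen.

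The other settings tried were DESeq2 size factors, DESeq2 1.42.0, no filter on low counts, a block for the replicate number, a fit of the compared groups only, limma on log2 of TPM plus 1 for genes at a TPM of 1 in 3 samples, a test against a 1.5-fold change, leaving out each library in turn, and the estimated correlation. Leaving out greater curvature 2 and corpus 1 together was added after the data were seen, as was the overlap between sites under the other settings. The overlap was set against 20 simulated sets with no change and shared normals, each gene drawn independently. Relations between scores over the 12 tumors were tested with 100000 permutations, and again with each score centered on its site mean, over all 1296 orders of the tumors within their sites, adjusted over the 7 relations, both chosen after the data were seen. Other splits of the samples were refitted, 100 for all tumors, 10 for each comparison of 3 with 3 and 60 for the comparisons between sites. The calls were tested on simulated data with known changes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the score tests and figures.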

Results

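RNA from 15 mouse stomach samples was sequenced in bulk, as 3 samples of normal tissue and 3 samples of tumor from each of 4 places: the antrum, the greater curvature side of the cardia, the lesser curvature side of the cardia, and the corpus. All samples carried the same genotype label, a tamoxifen-activated Cre under Pou2f3 (the master regulator of tuft cells, the chemosensory cells of the gut lining) with floxed Rb1 and Trp53 and a Cre-dependent, degradation-resistant Myc, and were collected 5 weeks after tamoxifen at 50 mg/kg. Samples are named here by site and replicate, as antrum 1 or normal 2. The part of the stomach from which the normal tissue came is not given. The labels call the replicates biological but do not say whether samples came from separate animals, so the p-values measure only the spread between these samples. Total counts ran from 7957165 in lesser curvature 2 to 21564972 in greater curvature 2. The normals held 14728541 to 17474336 counts, the antrum tumors 14307391 to 17213283 and the corpus tumors 15510193 to 17844668. In the normals the 10 most abundant genes took 19.5% to 24.6% of all counts, and Pgc, the pepsinogen of chief cells, took 4.44% to 9.77%. After the filter on low counts 16224 genes were tested. On the first principal component, with 46.9% of the variance, 10 of the 12 tumors lay on the far side of all 3 normals, while greater curvature 2 and corpus 1 lay among them, and the second component held 13.6%.

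**Figure D1:**
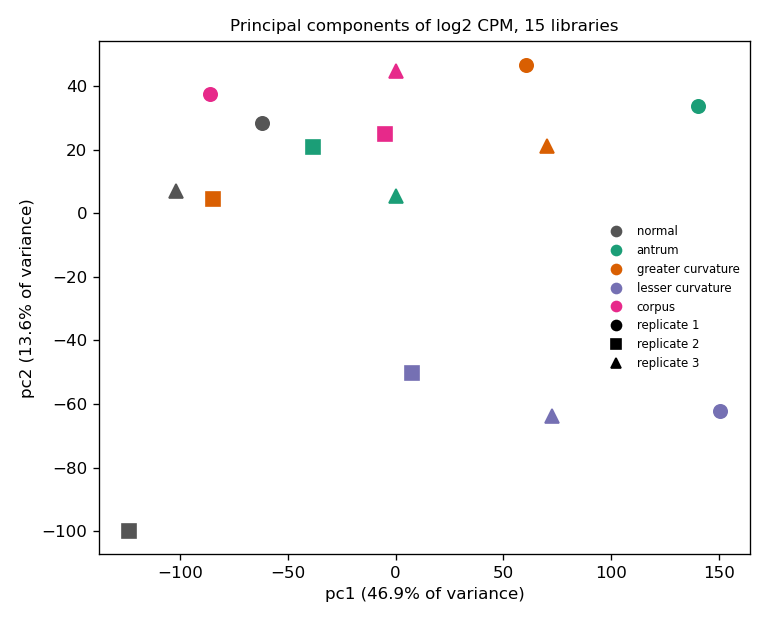
Principal components of log2 CPM (counts scaled to the library total) over the tested genes, with component 1 (46.9% of the variance) against component 2 (13.6%) and a point for each of the 15 libraries colored by group.

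The 4 genes of the engineered alleles were read first. Myc (chromosome 15, 61985391 to 61990374, GRCm38), a driver of growth and ribosome production, averaged 62.9 CPM ± 31.3 (SD, n = 3) in normals and 301 CPM ± 200.2 (SD, n = 12) in tumors. It rose by 2.13 on the log2 scale (SE 0.56, edgeR adjusted p = 0.0158), with 11 of 12 tumors above all normals. The call was lost without normal 2 (adjusted p = 0.0689) or without normal 3 (adjusted p = 0.0754), and whether transcripts of the Myc transgene counted toward Myc is not given in the sources used here. Rb1 (chromosome 14, 73183673 to 73325822), the brake on the E2F factors of S phase, had 491, 568 and 558 counts in the normals and 372 to 927 in the tumors, with a log2 fold change of -0.22 (adjusted p = 0.372). Trp53 (chromosome 11, 69580359 to 69591873), the stress-response factor p53, had a log2 fold change of 0.31 (adjusted p = 0.377), which passed the threshold with limma on the TPM table (adjusted p = 0.0177). The TPM table places the median gene 0.51 higher on the log2 scale in this comparison. Gene-level counts include exons outside the floxed segments, so these values do not test recombination. Pou2f3 (chromosome 9, 43123939 to 43210369) was scarce in every group, at 5, 61 and 8 counts in the normals and 2 to 54 in the tumors. Its log2 fold change of -1.20 (SE 0.84) had an adjusted p of 0.273.

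Tumors of all 4 sites were first set against the normals together, to ask what the tumors shared. All 28 DNA replication genes and all 21 mitosis genes listed rose, though as lists each had a camera adjusted p = 0.447 with an estimated correlation. The chemokine Cxcl5 of the series title and the matrix enzymes Mmp10 and Mmp13 rose too. All 11 smooth muscle markers fell, with an adjusted p = 0.447 with an estimated correlation for the list. Mmp10, a matrix metalloproteinase, went from 0.590 CPM ± 0.372 (SD, n = 3) to 73.4 CPM ± 31.9 (SD, n = 12), a log2 rise of 6.90 (SE 0.85, adjusted p = 0.000802). Onecut2, a transcription factor that controls cell identity, went from 3.39 CPM ± 1.67 to 65.9 CPM ± 27.3, a log2 rise of 4.21 (SE 0.40, adjusted p = 0.00053). Pln, the regulator of the calcium pump in muscle, went from 28.8 CPM ± 21.9 to 0.6 CPM ± 0.549, a log2 change of -5.68 (SE 0.67). Hand2, a transcription factor of gut mesenchyme and enteric nerves, changed by -4.52 (SE 0.48, adjusted p = 0.00053).

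By the rule for named genes, the 10 largest risers were Mmp10, Fgb, Cxcl5, Mmp13, Prss22, Cxcl1, Cxcl2, Onecut2, Inhba and Gls2. Fgb encodes the beta chain of fibrinogen, Mmp13 a collagenase, Prss22 a serine protease, Inhba the activin A subunit and Gls2 a glutaminase. Their log2 changes ran from 3.87 for Gls2 to 6.90 for Mmp10, and all 12 tumors lay above all 3 normals for each, as the rule requires. The 10 largest fallers were Inmt, Pln, Tacr2, Vip, Gkn3, Hand2, Fmo2, A4gnt, Azgp1 and Cartpt, with log2 changes from -5.72 to -3.97. Tacr2 is the neurokinin receptor of gut muscle, Vip and Cartpt are neuropeptides, and Gkn3 and A4gnt belong to gland mucous cells, A4gnt as the enzyme that completes their mucin sugars. Gkn3 went from 2107 CPM ± 2246 to 114 CPM ± 142 (SD, n = 3 and 12). Among these 20 genes the calls of Cxcl2 (adjusted p = 0.0503 without normal 3) and A4gnt (adjusted p = 0.0705 without normal 1) depended on a single library.

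Growth lists rose as whole lists in the pooled comparison. All 28 DNA replication genes of the Rb and E2F pathway rose over all genes tested and when adjusted over the list alone, with a median log2 change of 1.88. They include the helicase subunits Mcm4 (1.86, adjusted p = 0.000788) and Mcm3 (1.71), the replication factor Gins2 (1.91) and the methylation reader Uhrf1 (1.91). All 21 mitosis genes rose as well, also over the list alone, with a median of 2.30, including the spindle checkpoint kinases Bub1b (2.72, adjusted p = 0.000913) and Bub1 (2.50) and the transcription factor Foxm1 (2.26). All 22 Myc target genes of ribosome production rose, again over the list alone too, with a median of 1.59, among them Nop58 (1.59), Npm1 (1.76) and Cad (1.73), which makes pyrimidines. Camera, which sets a list against all other genes, gave adjusted p of 6.14e-17 for replication, 6.72e-15 for mitosis and 1.26e-10 for Myc targets. With an estimated correlation between genes the adjusted p were 0.447, 0.447 and 0.495. Fry, which asks only whether a list's members move one way, gave adjusted p of 0.000653, 0.000653 and 0.00358. The p53 target list had 2 of 18 members higher and 2 lower, or 1 and 1 adjusted over the list alone, with a camera adjusted p of 0.738. Bax, which promotes apoptosis, rose by 0.83 (adjusted p = 0.0229), a call lost without normal 1 (0.072), normal 2 (0.0943) or normal 3 (0.0605). Rrm2b, a ribonucleotide reductase subunit, changed by -0.64 (adjusted p = 0.0063) but by 0.02 in the TPM table.

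**Figure D2:**
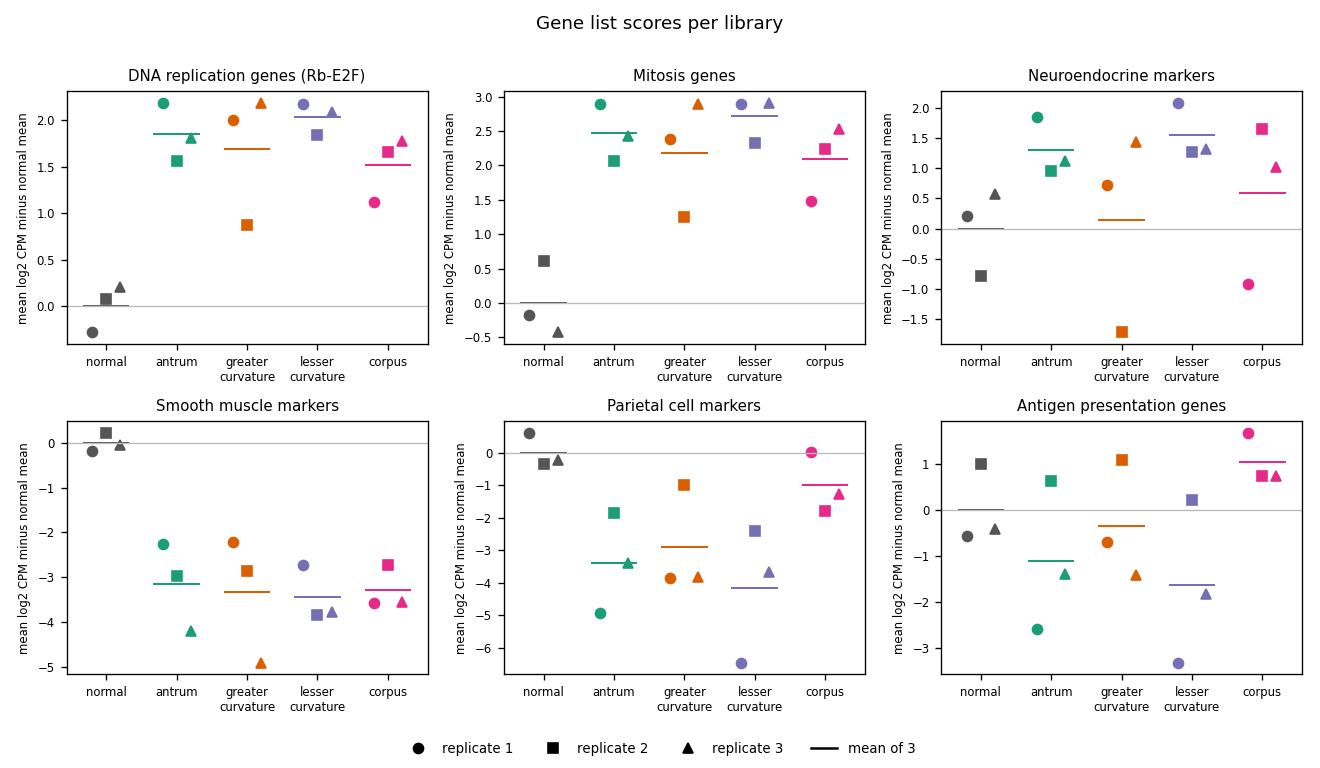
Scores of 6 gene lists in each library, as the mean log2 CPM of the list minus its mean in the normals, with points for libraries and bars for the mean of 3 per group. Replication and mitosis scores are above 0 in the tumor groups and smooth muscle scores below 0.

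The chemokines that act on the neutrophil receptor Cxcr2 rose with the tumors. Cxcl5 (chromosome 5, 90759360 to 90761624) averaged 0.326 CPM ± 0.230 (SD, n = 3) in normals, from 12 counts in all, and 20.3 CPM ± 23.9 (SD, n = 12) in tumors, with a range of 0.553 to 89.9. It rose by 5.71 on the log2 scale (SE 1.31, adjusted p = 0.00901), and all 12 tumors lay above the normals. Cxcl1 rose by 4.99 (adjusted p = 0.00481) and Cxcl3 by 5.30 (adjusted p = 0.00969). Of the 7 tested ligands and receptors 5 rose over all genes, and adjusted over the list alone 5 rose and 1 fell. The median was 4.44 and the camera adjusted p 0.0163, against an adjusted p = 0.495 with an estimated correlation. Cxcr2 itself (chromosome 1, 74153989 to 74161246) had 1.2 CPM ± 0.919 in normals and 1.89 CPM ± 1.36 in tumors, with a log2 change of 0.48 (SE 0.55, adjusted p = 0.498). Among neutrophil markers 3 of 10 rose over all genes and over the list alone, with a camera adjusted p of 0.0837, or 0.042 without lesser curvature 2. They included the inflammatory cytokine Il1b (3.52, adjusted p = 0.00694) and the gelatinase Mmp9 (3.17, adjusted p = 0.0214), whose call was lost without normal 1 (0.0635), normal 2 (0.0683) or normal 3 (0.0905). Of 14 macrophage and monocyte markers 7 rose and 1 fell, 8 and 1 adjusted over the list alone, with a camera adjusted p of 0.0163 and an adjusted p = 0.447 with an estimated correlation. The endotoxin co-receptor Cd14 rose by 1.75 (adjusted p = 0.00586) and the lysosomal protein Cd68 by 1.06 (adjusted p = 0.0101, or 0.0546 without normal 3).

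**Figure D3:**
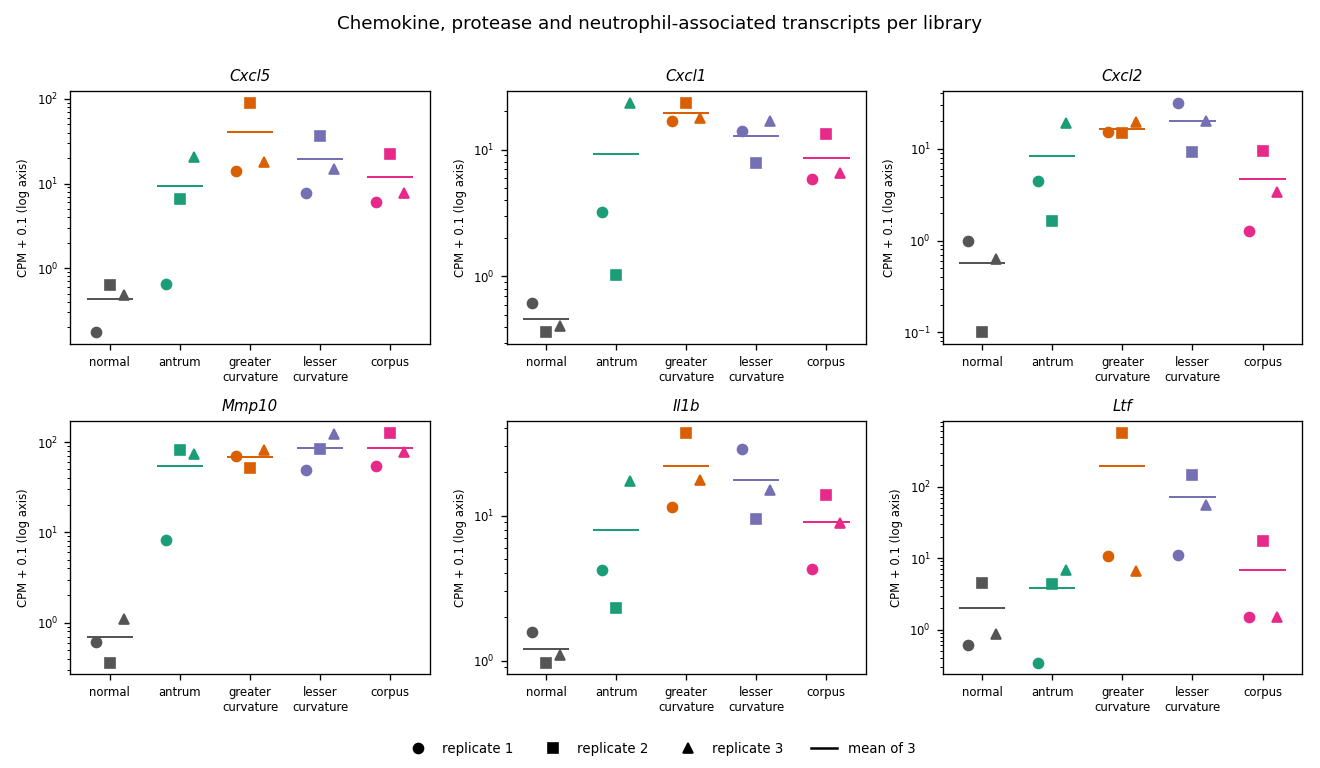
Expression of Cxcl5, Cxcl1, Cxcl2, Mmp10, Il1b and Ltf in each library, as CPM plus 0.1 on a log axis, by group. For Cxcl5, Cxcl1, Cxcl2 and Mmp10 each of the 12 tumors lies above the 3 normals.

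Neuroendocrine genes varied widely among the tumors, and few passed the pooled test. Of 27 markers 4 rose and 1 fell over all genes, and 1 rose and 1 fell adjusted over the list alone. The median log2 change was 1.75, and the camera adjusted p of 0.153 became 0.0367 without normal 3 and 0.0366 without greater curvature 2. The adhesion molecule Ncam1 rose by 1.61 (adjusted p = 0.0144), a call lost without normal 2 (0.0675) or normal 3 (0.0606). Ddc, which makes dopamine and serotonin from their precursors, rose by 2.96 (adjusted p = 0.031), a call lost without normal 1 (0.0943), normal 2 (0.117) or normal 3 (0.0667). Rab3b, a secretory vesicle protein, changed by -2.53 (adjusted p = 0.00319). Syp (chromosome X, 7638471 to 7653256), the vesicle protein synaptophysin, had 16.8 CPM ± 3.24 in normals and 63.5 CPM ± 35.7 in tumors, with 10 of 12 tumors above all normals. Its log2 change of 1.85 (SE 0.69) had an adjusted p of 0.0586, against 0.00854 by DESeq2, 0.0312 in the TPM table, 0.0486 without antrum 2, 0.00937 without greater curvature 2 and 0.0388 without corpus 1. Chga (chromosome 12, 102554969 to 102565028), the granule protein chromogranin A, had a log2 change of 1.32 (SE 0.99, adjusted p = 0.301). Neurod1 (chromosome 2, 79452521 to 79456751), a neural transcription factor, had a change of 1.79 (SE 1.12, adjusted p = 0.22). Within the greater curvature tumors Syp ran from 5.7 CPM in library 2 to 78.9 CPM in library 1. Among 12 gut hormones and their enzymes 4 fell, also adjusted over the list alone, with a camera adjusted p of 0.286, or 0.0469 without normal 1 and 0.00737 in the TPM table. They included Tac1, the precursor of substance P (-3.74, adjusted p = 0.00349), and Ghrl, the precursor of ghrelin (-2.72, adjusted p = 0.0205), which passed neither without normal 1 (0.0643) nor without normal 3 (0.0719). Of 17 tuft cell markers 1 rose and 1 fell, or 0 and 1 adjusted over the list alone, with a camera adjusted p of 0.155, or 0.0381 without normal 1. Dclk1 (chromosome 3, 55242364 to 55539068), a kinase of tuft cells, went from 14.5 CPM ± 5.67 to 30.5 CPM ± 12.9, a log2 rise of 0.98 (SE 0.32, adjusted p = 0.0359). That call was lost without normal 1 (0.137), normal 3 (0.128), antrum 3 (0.0514), greater curvature 3 (0.0531) or lesser curvature 3 (0.0524). Ptgs1, the constitutive cyclooxygenase, changed by -2.0 (adjusted p = 0.000779).

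**Figure D4:**
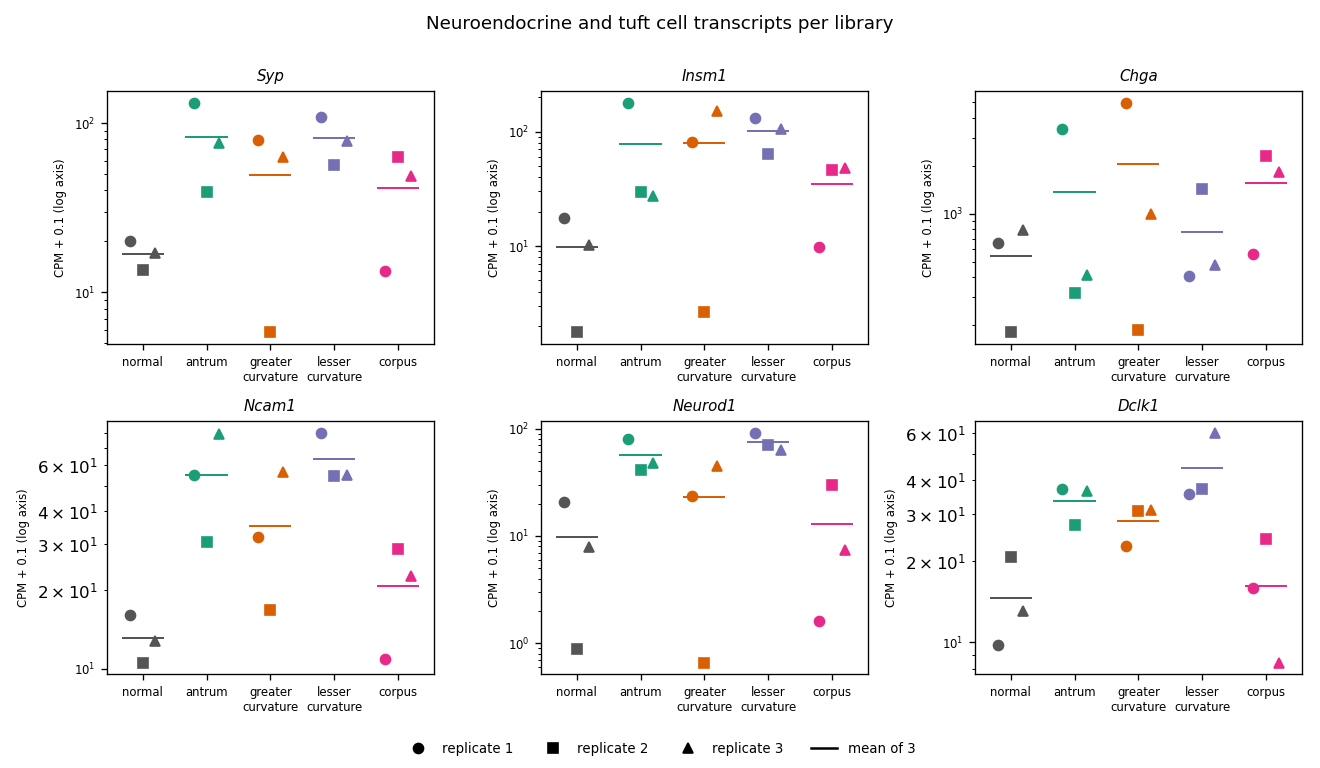
Expression of Syp, Insm1, Chga, Ncam1, Neurod1 and Dclk1 in each library, as CPM plus 0.1 on a log axis, by group. Syp spans 5.7 to 78.9 CPM within the greater curvature tumors.

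All 11 smooth muscle markers fell in the tumors, also adjusted over the list alone, with a median log2 change of -3.09. Acta2 and Mylk, parts of the contractile machinery, changed by -2.64 and -2.95 and the actin-binding Smtn by -2.27 (each adjusted p = 0.00053). The camera adjusted p was 7.62e-09, against an adjusted p = 0.447 with an estimated correlation. Of 11 enteric neuron and glia markers 5 fell and 1 rose, also over the list alone, with a camera adjusted p of 0.0225 and an adjusted p = 0.447 with an estimated correlation. The glial factor Sox10 changed by -3.47 (adjusted p = 0.00151) and Nos1, the nitric oxide synthase of enteric neurons, by -2.05 (adjusted p = 0.00816). The member that rose, named after its value was seen, was Elavl4, an RNA-binding protein of neurons (2.87, adjusted p = 0.0475). Its call held only without antrum 2, greater curvature 2 or corpus 1, and leaving out any other library gave adjusted p up to 0.155. The enteric list's call was lost without greater curvature 2 (0.051) and in the TPM table (0.0509). Markers of acid-secreting parietal cells fell, 6 of 10 over all genes and 9 adjusted over the list alone, with a median of -2.35. They included the histamine receptor Hrh2 (-3.23, adjusted p = 0.00816) and the potassium channel subunit Kcne2 (-3.35, adjusted p = 0.00913). The camera adjusted p was 0.000995, against an adjusted p = 0.531 with an estimated correlation. Of 10 pit and neck mucous cell markers 3 fell, also over the list alone, with a camera adjusted p of 0.0216 and an adjusted p = 0.655 with an estimated correlation. The mucin Muc6 changed by -5.12 (adjusted p = 0.00321) and the trefoil factor Tff2 by -3.46 (adjusted p = 0.0164), and without normal 1 these calls were lost (0.077 and 0.318). Of 5 chief cell markers 3 fell, also over the list alone, with a camera adjusted p of 0.0617, which passed without antrum 2 (0.0488) or lesser curvature 1, 2 or 3 (0.0252, 0.0322 and 0.0467) and in the TPM table (0.00102). Chia1, a stomach chitinase, changed by -4.91 (adjusted p = 0.0106) and Pgc by -3.92 (adjusted p = 0.0253), the latter lost without normal 1 (0.075), normal 2 (0.0508) or normal 3 (0.0665).

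The 3 normals differed in the stomach region their genes marked. Of 17 squamous markers of the forestomach, 16 were at least 10-fold higher in normal 2 than in the other normals. The keratin Krt13 had 1862 CPM in normal 2 and 0.0734 and 0.153 CPM in normals 1 and 3. In the pooled comparison 11 of 17 squamous markers fell, or 13 with 1 rising adjusted over the list alone, with a median of -4.07 and a camera adjusted p of 0.698, or 0.0127 in the TPM table. Without normal 2 the list reversed to higher (adjusted p = 0.000481), and so did its members Lor, a cell envelope protein (-8.69 with all samples, 0.37 without normal 2), and Krt4 (-6.98 and 3.81). Gast, the gastrin of the antrum, had 604 CPM in normal 3, 37 in normal 2 and 0 in normal 1. The 3 antral gland markers fell, also over the list alone, with a camera adjusted p of 0.183, or 0.0113 without normal 1 and 0.0175 in the TPM table. Among them Pdx1, a factor of the antrum and duodenum, changed by -3.08 (adjusted p = 0.0164), a call lost without normal 2 (0.0636) or normal 3 (0.0965).

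**Figure D5:**
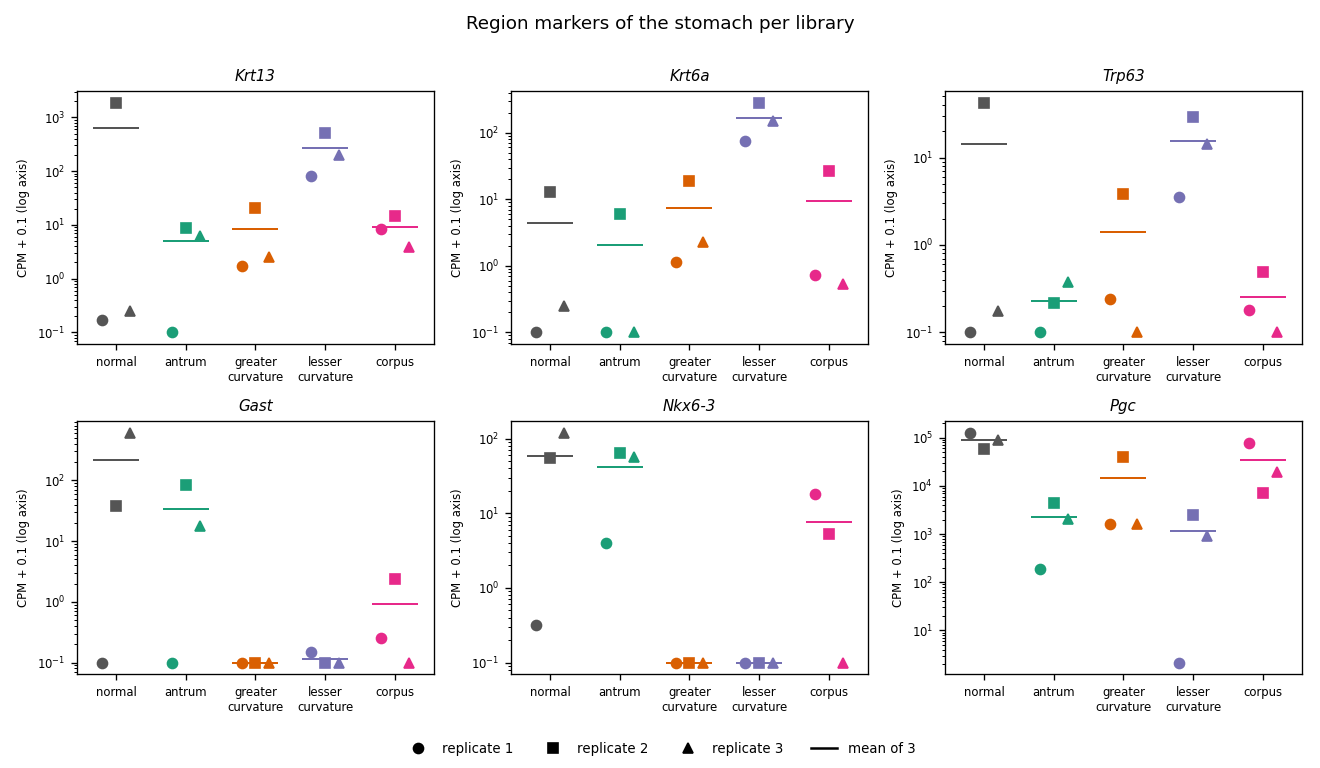
Expression of Krt13, Krt6a, Trp63, Gast, Nkx6-3 and Pgc in each library, as CPM plus 0.1 on a log axis, by group. Krt13 is at 1862 CPM in normal 2 and at 79.8 to 516 CPM in the lesser curvature tumors.

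Other lists showed few changes in the pooled comparison. Of 13 fibroblast and matrix genes 2 rose, or 1 adjusted over the list alone (camera adjusted p = 0.153). The growth factor receptor Pdgfrb rose by 1.64 (adjusted p = 0.00277). Collagen gene Col1a1 rose by 2.39 (adjusted p = 0.0392), a call lost without normal 1 (0.0986), normal 2 (0.0834), normal 3 (0.144), antrum 3 (0.0543), lesser curvature 3 (0.0528), corpus 2 (0.056) or corpus 3 (0.0591). Of 7 mesenchymal transition genes 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0686, or 0.0407 without normal 2, 0.0455 without greater curvature 1 and 0.0499 in the TPM table), including the neural cadherin Cdh2 (2.67, adjusted p = 0.00198). Of 10 endothelial markers 2 fell, also over the list alone (camera adjusted p = 0.129, or 0.0175 without normal 2). Vwf, which binds platelets, changed by -1.06 (adjusted p = 0.0296), lost without normal 1 (0.181) or normal 3 (0.116) and in the TPM table (0.248). T and NK cell markers had 1 of 3 tested members higher, also over the list alone (camera adjusted p = 0.34). It was the co-receptor Cd4 (1.74, adjusted p = 0.0108), lost without normal 1 (0.0514) or normal 3 (0.0527). None of 6 B and plasma cell markers, 9 mast cell markers, 11 pan-epithelial markers or 13 antigen presentation genes passed either way or over the list alone. Their camera adjusted p were 0.517, 0.171, 0.588 and 0.341, and in the TPM table mast cell markers (0.00867) and antigen presentation genes (0.037) passed. Of 11 intestinal markers 1 rose, or 0 adjusted over the list alone (camera adjusted p = 0.501, or 0.0394 in the TPM table). That marker, the cadherin Cdh17 (4.89, adjusted p = 0.0467), held only without antrum 1, greater curvature 2 or lesser curvature 1, and leaving out any other library gave 0.0505 to 0.141. Of 9 pancreatic acinar markers 1 fell, also over the list alone (camera adjusted p = 0.445), the lipase cofactor Clps (-3.66, adjusted p = 0.0191), lost without normal 1 (0.0521) or normal 3 (0.0641). Of 4 adipocyte markers 2 fell, also over the list alone (camera adjusted p = 0.0617, or 0.0403 without normal 1, 0.0393 without lesser curvature 2, 0.0263 without corpus 2 and 0.0137 in the TPM table), including the lipase Lipe (-1.05, adjusted p = 0.0101), lost without normal 2 (0.0504) and in the TPM table (0.153). Of 5 erythroid genes 2 fell, or 4 adjusted over the list alone (camera adjusted p = 0.183, or 0.000995 without normal 2), including the globin Hba-a2 (-1.20, adjusted p = 0.0302), lost without normal 1 (0.0893) or normal 3 (0.272) and in the TPM table (0.507). Of 15 interferon response genes 1 rose, or 0 adjusted over the list alone (camera adjusted p = 0.517). The chemokine Cxcl10 (1.54, adjusted p = 0.0478) held only without antrum 1, 2 or 3 or greater curvature 2, and leaving out any other library gave 0.0512 to 0.167. Of 15 glycolysis and hypoxia genes 1 fell, or 0 adjusted over the list alone (camera adjusted p = 0.341). It was Aldoa (-0.50, adjusted p = 0.02), an aldolase, a call lost without normal 2 (0.0674) or normal 3 (0.106), and in the TPM table its direction turned, to a log2 change of 0.07. The lists written as signs of handling and RNA quality moved with the comparison too. Neither handling nor RNA quality was measured, and what lowered these genes was not tested. Of 12 immediate early genes 5 fell, also over the list alone, with a camera adjusted p of 0.0261, an adjusted p = 0.567 with an estimated correlation and 0.19 without normal 2. The antiproliferative gene Btg2 changed by -0.83 (adjusted p = 0.00312, or 0.124 in the TPM table). Of 11 mitochondrially encoded genes 6 fell, or 8 adjusted over the list alone, with a camera adjusted p of 0.000969 and an adjusted p = 0.495 with an estimated correlation. The complex I gene mt-Nd4 changed by -1.2 (adjusted p = 0.00574). Mitochondrial genes took 6.89% ± 2.15 of counts in normals and 5.42% ± 1.69 (antrum), 5.06% ± 1.31 (greater curvature), 4.94% ± 1.23 (lesser curvature) and 4.73% ± 0.356 (corpus) in tumors (SD, n = 3 each).

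The pooled edgeR test called 5176 of 16224 genes, or 31.9%, with 2628 higher and 2548 lower in tumors, and 7480 genes had an unadjusted p under 0.05. Leaving out 1 normal moved the count by over 1.5 times, to 3102 (normal 1), 2890 (normal 2) and 2587 (normal 3). The TPM table places the median gene 0.51 higher on the log2 scale than the scaling used here does, and there 5739 genes were higher and 551 lower. The direction of the smooth muscle, parietal, pit and neck, enteric, immediate early, mitochondrial, replication, Myc target, mitosis, CXCR2 and macrophage medians was the same in both.

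Antrum tumors were set against normal tissue to ask how tumors of that site differed from it. The stomach region of the normals is not given, so each site may differ from them by region as well as by tumor. The site comparisons with normal cannot tell these apart. The matrix enzyme Mmp10 rose by 6.49 (SE 0.88, adjusted p = 0.0106). Dlk1, a Notch-related protein of progenitor and endocrine cells, rose by 5.36 (SE 0.94, adjusted p = 0.0114), from 2.22 CPM ± 1.49 to 91.8 CPM ± 23.1 (SD, n = 3 each), and neither call was lost without any single library. Calcr, the calcitonin receptor, rose by 8.02 and the transcription factor Shox2 by 5.24. Zdbf2, an imprinted gene, rose by 5.27 (adjusted p = 0.0211), from 1.5 CPM ± 0.314 to 58.2 CPM ± 18.6. The 5 falling genes named by the rule were Lor, Dapl1, Pla2g4f, Aox4 and Klk8, genes of which normal 2 held most of the counts in normals. Dapl1 had 0 counts in the antrum tumors, at least 265-fold lower than the normals at a floor of 3 counts over the group, or at least 8.42-fold without normal 2. All 28 replication genes rose (median 1.90, camera adjusted p = 3.4e-18, adjusted p = 0.546 with an estimated correlation), as did all 21 mitosis genes (median 2.41). Smooth muscle markers fell, 8 of 11 (median -2.76, camera adjusted p = 2.11e-08, adjusted p = 0.546 with an estimated correlation). Among CXCR2 ligands and receptors 4 of 7 rose, also over the list alone, among them Cxcl1 (4.62, adjusted p = 0.0181), with a camera adjusted p of 0.0767, or 0.0194 without antrum 1 and 0.039 without antrum 2. Of 27 neuroendocrine markers 1 rose and 1 fell, or 1 and 0 over the list alone. The list was called higher (median 1.97, camera adjusted p = 0.0462, adjusted p = 0.757 with an estimated correlation), a call lost without normal 2 (0.115) or antrum 1 (0.0796) and in the TPM table (0.361). Ncam1 rose by 2.07 (adjusted p = 0.0229), a call lost without any single normal or without antrum 1 or antrum 3 (0.0534 to 0.0696). The antral gland list had a negative median (-0.49) while camera pointed higher (adjusted p = 0.974). Mitochondrial genes were lower here too (camera adjusted p = 0.0021, adjusted p = 0.558 with an estimated correlation), and immediate early genes had a camera adjusted p of 0.0502, which passed without any 1 of 9 libraries (0.0054 to 0.0486) and with DESeq2 size factors (0.048).

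For the antrum tumors edgeR called 2380 genes, 1556 higher and 824 lower. The count was 4439 by DESeq2, 4047 in the TPM table and 902 with only the 6 samples fitted. It fell to 735, 933 and 387 without normal 1, 2 and 3, 455 without antrum 1, 649 without antrum 3 and 1559 without lesser curvature 3. Shox2's call was lost without normal 3 (0.0722), antrum 1 (0.0645) or antrum 3 (0.0559), Zdbf2's without any normal or antrum 3 (0.0527 to 0.0703), and Calcr's without any normal, antrum 3, lesser curvature 3, corpus 2 or corpus 3 (0.0535 to 0.113). Cxcl1's was lost without any normal (0.052 to 0.0638), and those of Lor (0.205), Dapl1 (0.0568), Aox4 (0.398) and Klk8 (0.443) without normal 2, while the 5 falling genes also lost theirs without antrum 1 (0.066 to 0.121) or antrum 3 (0.0565 to 0.0978), and Lor, Aox4 and Klk8 without antrum 2 (0.0568, 0.0733 and 0.0626).

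In the greater curvature tumors Cxcl5 averaged 40.6 CPM ± 42.7 (SD, n = 3), with 13.8 and 18.1 CPM in libraries 1 and 3 and 89.9 CPM in library 2. Against normal, Cxcl5 rose by 6.95 (SE 1.44, adjusted p = 0.0207), Mmp13 by 7.08 (SE 1.29, adjusted p = 0.0152) and Mmp10 by 6.82 (SE 0.89, adjusted p = 0.00891). Gabrp, a GABA receptor subunit, averaged 11 CPM ± 2.34 against 2 counts in the 3 normals together, and Cdh17 averaged 16.8 CPM ± 14.8 (adjusted p = 0.05). Among CXCR2 ligands and receptors 4 of 7 rose, or 5 over the list alone (median 5.07, camera adjusted p = 0.000617, adjusted p = 0.342 with an estimated correlation). Of 10 neutrophil markers 3 rose, or 4 over the list alone (camera adjusted p = 0.005, adjusted p = 0.342 with an estimated correlation), and of 14 macrophage markers 3 rose, or 8 with 1 falling over the list alone (camera adjusted p = 0.00417, adjusted p = 0.342 with an estimated correlation). Both immune lists lost their calls without greater curvature 2 (0.071 and 0.063), and the neutrophil list in the TPM table too (0.0551). Il1b rose by 4.29 (adjusted p = 0.0175) and Cd14 by 2.52 (adjusted p = 0.0147). Replication genes rose, 27 of 28 (median 1.81, camera adjusted p = 1.09e-17, adjusted p = 0.342 with an estimated correlation), and all 21 mitosis genes rose (median 2.24). Smooth muscle genes fell, 8 of 11 (median -2.87, camera adjusted p = 4.67e-10, adjusted p = 0.342 with an estimated correlation). Mean log2 scores of gland markers lay below the normals too, at -2.88 ± 1.94 (chief), -2.89 ± 1.63 (parietal) and -2.64 ± 1.65 (pit and neck, SD, n = 3). The neuroendocrine list had a median of 1.32 and a mean of 0.73 while camera pointed lower (adjusted p = 0.94), with 0 members higher and 1 lower. Gast had 0 counts in these tumors, as in normal 1. Against the mean of the normals, most of it from normal 3, that is at least 3780-fold lower at the 3-count floor over the group, or at least 328-fold without normal 3. Pln changed by -6.49 (adjusted p = 0.0156), the iron reductase Cybrd1 by -6.15, and the squamous genes Lor, Dapl1 and Klk8 by -11.34, -8.42 and -7.93. Mitochondrial genes were lower (3 of 11, camera adjusted p = 0.000599, adjusted p = 0.37 with an estimated correlation), and immediate early genes had a camera adjusted p of 0.0731, or 0.0246 without normal 1 and 0.0407 without normal 3.

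EdgeR called 1503 genes in the greater curvature tumors, 1055 higher and 448 lower, against 3800 by DESeq2, 3153 in the TPM table, 964 without the low-count filter and 4 with only the 6 samples fitted. The count moved to 238, 457 and 1 without normal 1, 2 and 3, 111 without greater curvature 1, 19 without greater curvature 3, 957 without antrum 3, 801 without lesser curvature 3, 972 without corpus 2, 933 without corpus 3, and up to 4173 without greater curvature 2. Each gene named above for this site lost its call without at least 1 library: Mmp10 without normal 3 (0.0507), Mmp13 without normal 1, normal 3 or greater curvature 3 (0.0513 to 0.0676), Cxcl5 without any normal or greater curvature 1 or 3 (0.0506 to 0.0747), Il1b without any normal or greater curvature 3 (0.0538 to 0.0727), Cd14 without normal 3 (0.0669) or greater curvature 3 (0.0513), Pln without normal 3 (0.0676), greater curvature 1 (0.065) or greater curvature 3 (0.0648), and Gabrp, Cdh17, Cybrd1, Lor, Dapl1 and Klk8 without any 1 of normal 2, normal 3, greater curvature 1, greater curvature 3 and lesser curvature 3 (0.0502 to 0.432), among others.

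Lesser curvature tumors were set against normal in the same way. Mmp10 rose by 7.14 (SE 0.90, adjusted p = 0.00338) and Mmp13 by 5.92 (SE 1.23, adjusted p = 0.0071). Cxcl1, Cxcl2, Cxcl3 and Cxcl5 rose by 5.11, 5.37, 5.74 and 5.89 (adjusted p from 0.00637 to 0.0112). Col10a1, a collagen of growth cartilage, averaged 21.4 CPM ± 23 (SD, n = 3) against 1 count in the 3 normals, and the cartilage collagen Col2a1 averaged 12.1 CPM ± 9.91 against 3 counts. Peg10, an imprinted gene of retroviral origin, rose by 6.07 (adjusted p = 0.0194). Of 7 CXCR2 ligands and receptors 5 rose and 1 fell, also over the list alone (camera adjusted p = 0.0134, adjusted p = 0.447 with an estimated correlation). Neuroendocrine markers had 5 of 27 higher and 1 lower, or 1 and 1 over the list alone. The list was called (median 2.27, camera adjusted p = 0.0384, adjusted p = 0.59 with an estimated correlation), a call lost without normal 1 (0.0598), normal 2 (0.133) or lesser curvature 1 (0.105) and in the TPM table (0.509). Ncam1 rose by 2.27 (adjusted p = 0.00813). Replication (28 of 28, median 2.04, camera adjusted p = 1.26e-14), mitosis (21 of 21, median 2.57) and Myc target genes (22 of 22, median 1.94) all rose, with an adjusted p = 0.447 with an estimated correlation for each. Il1b rose by 3.98 (adjusted p = 0.00727), and the neutrophil list, with 4 of 10 higher, was called (camera adjusted p = 0.0214, adjusted p = 0.447 with an estimated correlation), a call lost without normal 2 (0.0517) and in the TPM table (0.137). Gland markers fell, with 5 of 10 parietal markers (median -3.74, camera adjusted p = 0.000451, adjusted p = 0.447 with an estimated correlation), 3 of 5 chief cell markers (median -5.56, camera adjusted p = 0.0133, adjusted p = 0.447 with an estimated correlation) and 3 of 10 pit and neck markers (median -2.83, camera adjusted p = 0.00383, adjusted p = 0.513 with an estimated correlation). Muc6 changed by -7.37 (SE 1.72, adjusted p = 0.0107), from 18740 CPM ± 28171 to 113 CPM ± 91.5 (SD, n = 3 each). The normals ran from 2236 to 51268 CPM, so the size of this fall depends mostly on a single normal. The antral factor Nkx6-3 had 0 counts, at least 975-fold lower than in the normals at the 3-count floor over the group, or at least 463-fold without normal 3. Normal 1 held only 0.22 CPM of Nkx6-3, so these bounds rest on normals 2 and 3. Prap1, Chia1 and Zg16, secreted proteins of the gut lining, changed by -8.85, -7.82 and -7.64. All 11 smooth muscle markers fell (median -3.31, camera adjusted p = 7.11e-07, adjusted p = 0.447 with an estimated correlation). The squamous list had a median of -0.41 and a mean of -0.28 with 0 of 17 members called, while camera pointed higher (adjusted p = 0.0214, adjusted p = 0.59 with an estimated correlation). Immediate early genes (4 of 12, camera adjusted p = 0.00822) and mitochondrial genes (5 of 11, camera adjusted p = 0.00215) were lower here too, each with an adjusted p = 0.447 with an estimated correlation.

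EdgeR called 5445 genes in the lesser curvature tumors, 2955 higher and 2490 lower, and 2815, 2159 and 2439 without normal 3, lesser curvature 1 and lesser curvature 3. Calls were lost for Col2a1 without normal 2 (0.0578) or normal 3 (0.0639), Peg10 without those or lesser curvature 1 (0.0544 to 0.0688), Prap1 without normal 3 (0.213), lesser curvature 1 (0.0799) or lesser curvature 3 (0.0748), Chia1 without the same libraries (0.0552, 0.0566 and 0.0798), Zg16 without normal 3 (0.462) or any lesser curvature library (0.0644 to 0.0999), Nkx6-3 without normal 2, normal 3 or any lesser curvature library (0.0527 to 0.0913), and the squamous list without normal 1 (0.186), normal 3 (0.123) or lesser curvature 2 (0.0795) and in the TPM table (0.531).

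Corpus tumors were set against normal last. Mmp10 rose by 7.16 (SE 0.90, adjusted p = 0.00832), Fgb by 6.55 (SE 1.39, adjusted p = 0.0341) and Gls2 by 4.73 (SE 0.95, adjusted p = 0.0298). Prss22 rose by 5.19 and Hamp, the iron hormone hepcidin, by 4.55, from 0.617 CPM ± 0.234 to 14.7 CPM ± 10.5 (SD, n = 3 each). Fmo2, a flavin monooxygenase, changed by -5.47 (SE 0.85, adjusted p = 0.0195), Pln by -5.82, Inmt by -5.72, Cartpt by -5.34 and Elmod1 by -7.35. Elmod1 ran from 1.03 to 30.9 CPM in the normals, at a mean of 11.1 CPM, so the size of its fall depends mostly on a single normal. Of 28 replication genes 16 rose and of 21 mitosis genes 16 rose, and all 28 and all 21 did adjusted over the list alone (medians 1.60 and 2.03, camera adjusted p = 3.54e-19 and 7.76e-18, adjusted p = 0.32 with an estimated correlation for both). Among Myc targets 1 of 22 rose over all genes and 21 over the list alone. The spindle kinase Bub1b rose by 2.48 (adjusted p = 0.0195). Of 7 CXCR2 ligands and receptors 1, Cxcl1, rose (4.52, adjusted p = 0.0386), or 4 over the list alone, and Cxcl5 had a log2 change of 5.18 (adjusted p = 0.0554). The list was called (camera adjusted p = 0.0441, adjusted p = 0.634 with an estimated correlation), a call lost without normal 3 (0.0504), greater curvature 2 (0.0797), greater curvature 3 (0.0584) or corpus 2 (0.0679) and in the TPM table (0.114). Smooth muscle markers fell, 8 of 11 (median -3.06, camera adjusted p = 1.08e-12, adjusted p = 0.32 with an estimated correlation), and enteric markers fell, 2 of 11 or 4 over the list alone (median -2.88, camera adjusted p = 7.44e-05, adjusted p = 0.0983 with an estimated correlation). Pancreatic acinar markers had 0 of 9 members called, a median of 3.70 and a camera adjusted p of 0.00573 (adjusted p = 0.634 with an estimated correlation), lost without normal 2 (0.0685) or corpus 1 (0.0912). Parietal markers had 0 of 10 called (median -0.79, camera adjusted p = 0.139, or 0.0492 without corpus 1 and 0.00494 in the TPM table). Mitochondrial genes were lower as a list (0 of 11 called, camera adjusted p = 0.000783, adjusted p = 0.571 with an estimated correlation), and immediate early genes had a camera adjusted p of 0.102, or 0.0189 without normal 1, 0.0387 without normal 3 and 0.0159 without corpus 1.

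EdgeR called 574 genes in the corpus tumors, 381 higher and 193 lower, against 2192 by DESeq2, 331 without the low-count filter and 301 with only the 6 samples fitted. Leaving out single libraries moved the count to 26, 227 and 16 (normal 1, 2 and 3), 279 (antrum 3), 208 (greater curvature 1), 1218 (greater curvature 2), 270, 377 and 134 (lesser curvature 1, 2 and 3), and 925, 17 and 0 (corpus 1, 2 and 3). Without corpus 3 the 10 genes named by the rule and Bub1b and Cxcl1 all lost their calls, with adjusted p from 0.0509 for Mmp10 to 0.18 for Elmod1. Without corpus 2 each but Mmp10 lost its call (0.0707 to 0.135), and without normal 1 or normal 3 each but Mmp10 did as well (0.0555 to 0.129), and single genes also lost theirs without further libraries.

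The same genes changed in several sites. Higher in each of the 4 sites were 16 of 21 mitosis genes and 16 of 28 replication genes, and 8 of 11 smooth muscle genes were lower in each. In 2 or more sites 2405 genes were called the same way, 1588 higher and 817 lower, and 345 higher and 131 lower genes were called in all 4 sites. No gene was called in opposite directions in any pair of sites. The antrum and lesser curvature tumors shared 1491 higher and 699 lower genes, against 283 and 126 for independent lists of those sizes. The 4 comparisons share the same 3 normals, which cannot be split further. Simulated groups with no change, set against the same normals, shared 0.1 genes on average. They had only 0.3 genes called in any site on average, so there was almost nothing to share. That value thus cannot show how far shared normals raise the overlap where many genes are called. The simulation drew each gene independently, without correlation between genes, differences in tissue make-up or samples that shift together. It thus covers counting error and the spread of single genes only. Log2 fold changes of pairs of sites correlated at 0.644 to 0.893 across genes, which are not independent replicates, against 0.501 to 0.506 in the simulation. Their covariance exceeded the simulated one by 1.07 to 1.81. The shared count was 694, 951 and 348 without normal 1, 2 and 3, 1024 without antrum 3, 1380 without lesser curvature 3 and 4248 without greater curvature 2.

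The 4 tumor sites were compared with each other to ask which genes mark a site. Squamous keratins stood out in the lesser curvature tumors and antral genes in the antrum tumors. In the fit of all 15 samples, with a single exception, no gene passed the test over all genes. That exception was Sprr2h, a cornified envelope gene of squamous epithelium, higher in the lesser curvature tumors than in the other 3 sites (adjusted p = 0.024), at 2.18 CPM on average against 0 in the antrum, 0.0809 in the greater curvature and 0.0187 in the corpus. That call was lost without normal 1, antrum 3 or any greater curvature, lesser curvature or corpus library (0.0527 to 0.22). Krt16, picked after its values were seen, had 57.2, 245 and 124 CPM in the lesser curvature tumors and 0 to 7.79 in the other 9 (adjusted p = 0.206). The squamous list was higher in the lesser curvature tumors, 16 of 17 members adjusted over the list alone (median 5.62, camera adjusted p = 1.39e-11, adjusted p = 0.546 with an estimated correlation). Pit and neck markers (median -1.74, camera adjusted p = 0.000593, or 0.0816 without lesser curvature 1) and antigen presentation genes (median -1.30, camera adjusted p = 0.000262) were lower there, each with an adjusted p = 0.546 with an estimated correlation. Immediate early genes, listed as a sign of handling, were lower there as well (median -0.57, camera adjusted p = 0.00333, adjusted p = 0.546 with an estimated correlation).

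In the antrum tumors the 3 antral gland markers were higher than in the other sites adjusted over the list alone (camera adjusted p = 1.15e-06, adjusted p = 0.128 with an estimated correlation). Nkx6-3 had 3.87, 63.7 and 56.8 CPM there, 0 in all 6 curvature tumors and 17.8, 5.21 and 0 in the corpus tumors. Pax6, a factor of endocrine cells picked after its values were seen, had 19.4, 62.9 and 144 CPM in the antrum tumors and 0.306 to 21.3 in the other 9 (adjusted p = 0.254). The neuroendocrine list was higher there (median 0.57, camera adjusted p = 0.000155, adjusted p = 0.67 with an estimated correlation), a call lost without antrum 1 (0.329) or greater curvature 2 (0.0841). That list was also called higher in the lesser curvature tumors than in the other sites (median 0.62, camera adjusted p = 0.00371, adjusted p = 0.555 with an estimated correlation), a call lost in the TPM table (0.173). In the greater curvature tumors the CXCR2 list (median 0.95, camera adjusted p = 1.94e-05) and the neutrophil list (median 0.98, camera adjusted p = 1.21e-05) were higher and the neuroendocrine list lower (median -0.26, camera adjusted p = 1.02e-09). Their adjusted p with an estimated correlation were 0.449, 0.449 and 0.467, and all 3 calls were lost without greater curvature 2 (0.0913, 0.0682 and 0.763). Immediate early genes were higher there too (median 0.17, camera adjusted p = 0.0383, adjusted p = 0.686 with an estimated correlation). The neutrophil list was also called higher in the lesser curvature tumors (median 0.95, camera adjusted p = 0.0109, adjusted p = 0.546 with an estimated correlation), a call lost in the TPM table (0.0591). Ltf, the neutrophil granule protein lactoferrin, had 566 CPM in greater curvature 2 and 10.7 and 6.54 in greater curvature 1 and 3.

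Acid and enzyme gland genes were higher in the corpus tumors than in the other tumors by the list test. Parietal markers were higher (median 1.86, 6 of 10 over the list alone, camera adjusted p = 1.43e-06), as were chief cell markers (median 2.36, 0 over the list alone, camera adjusted p = 0.00201), each with an adjusted p = 0.353 with an estimated correlation. The proton pump gene Atp4a had 4175, 995 and 1446 CPM in the corpus tumors and 12.2 to 1716 in the others. Interferon response genes (median 2.09, 2 of 15 over the list alone) and antigen presentation genes (median 1.45, 0 of 13) were higher too, each with a camera adjusted p of 8.83e-08, and with an adjusted p = 0.353 and 0.363 with an estimated correlation. Between the curvatures the squamous list was lower in the greater curvature (median -4.53, camera adjusted p = 7.85e-10) and acinar markers higher (median 4.81, 3 of 9 over the list alone, camera adjusted p = 3.75e-07), each with an adjusted p = 0.656 with an estimated correlation. The amine oxidase Maob, picked after its values were seen, had 2.79, 6.16 and 3.45 CPM in the greater and 21.3, 28.3 and 28.9 CPM in the lesser curvature tumors (adjusted p = 0.3).

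Over the 4 sites together edgeR called 0 genes, with 947 at an unadjusted p under 0.05, and DESeq2 called 165. Against the other 3 sites edgeR called 0 genes for the antrum (369 unadjusted, 68 by DESeq2), 0 for the greater curvature (365 and 26), 1 for the lesser curvature (1763 and 244) and 0 for the corpus (1218 and 63), and 0 between the curvatures (889 and 83). Fitted on the tumors alone, edgeR called 117 genes for the lesser curvature against the other sites and 12 over the 4 sites. Without normal 2 the lesser curvature count was 144 and the count over the 4 sites 16. The fit of all samples takes the spread of each gene from the normals too. Its low counts thus do not show that the sites are alike. Without normal 1, antrum 3, any greater curvature library, lesser curvature 1, lesser curvature 3 or corpus 1 the lesser curvature count was 0, and without corpus 2 the count was 1 for each of the other sites. On simulated data with known changes the lesser curvature test against the other sites recovered 62% of 4-fold and 17% of 2-fold changes. Each gene was drawn independently there, without samples that shift together, and low-count genes were left unchanged. These shares thus need not hold for the real samples. Of 33 lists camera called 4 higher and 8 lower for the antrum against the other sites, 11 and 7 for the greater curvature, 6 and 8 for the lesser curvature, 8 and 8 for the corpus, and 11 and 5 between the curvatures, of which only some are named above. With an estimated correlation 0 of them were called. No list was called by fry in any comparison between sites.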

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

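The tests of muscle wall, scaling, dilution, region markers and tumor spread in this part were chosen after those results were seen, while the splits of the samples were planned. After their values were seen, the forestomach test and the splits with a real count of 0 were changed from fitting their explanation to undecided.

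Sprr2h was called higher in the lesser curvature tumors than in the other 3 sites, a difference between groups, with a fitted log2 change of 6.37 (edgeR adjusted p = 0.024). It was higher in 3 of 3 lesser curvature tumors, at 29, 24 and 51 counts. The antrum tumors were at 0, so the fitted change depends on the prior count. The call was lost without normal 1 (0.0527), antrum 3 (0.056), any greater curvature library (0.0793, 0.11 and 0.0688), any lesser curvature library (0.0829, 0.0556 and 0.22) or any corpus library (0.115, 0.0633 and 0.0556). Its Sprr2 relatives are near identical in sequence, and how reads were shared among them was not tested.

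Smooth muscle genes were lower and growth genes higher in the tumors. Library scaling alone does not account for this, since the smooth muscle median was still -2.43 in the mildest of 4 scalings. Dilution by the loss of muscle RNA does not account for the growth genes if it raises all other lists alike. The replication median lay 2.36 above the endothelial one, with a spread of 0.65. The mean endothelial score itself fell in each site (-0.338 to -0.741), so that list may not be a neutral standard. Other lists rose, such as the macrophage (0.329 to 0.864) and neutrophil scores (0.221 to 2.21), against 1.52 to 2.04 for replication. The gap thus depends on the list chosen, and dilution as part of the rise stays open. Less muscle wall in the tumor samples may explain the muscle part, as the enteric list had a median of -1.42 (-0.18 in the TPM table). A fall of muscle genes within the wall stays open as well, since no value here counts cells.

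Region markers differed among the 3 normal samples. Whether normal 2 holds forestomach lining stays open, since the share of squamous markers at least 10-fold higher there than in the other normals (94.1%, 16 of 17) restates the pattern. Squamous tissue with the same proportions of these genes as in normal 2 is argued against in the lesser curvature tumors. The log2 ratios of the members to normal 2 spread with an SD of at least 1.93 in each lesser curvature library. How far such proportions vary between samples of the same tissue was not measured. Lesser curvature 1 and 2 differed from each other as well (Krt1 at -6.77 and -2.32, Krt4 at -4.53 and -3.59). The same tissue as in normal 2 is thus not excluded. Tissue of another place or state in those tumors stays open, and no biological explanation was tested.

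Tumors of one site differed widely. Different shares of gastric mucosa in the samples may explain part of this, since the mucosa score was lower where the replication score was higher over the 12 tumors (Pearson r = -0.788, permutation p = 0.00382, adjusted p = 0.00891, n = 12, Spearman -0.930, and -0.912 without antrum 1 and lesser curvature 1). With both scores centered on their site means r was -0.72 (exact p = 0.00154, adjusted p = 0.0054, n = 12), and -0.678 at the weakest, without antrum 1. These p-values treat the 12 tumors as independent. Antrum and curvature tumors of the same replicate number tended to shift together, so the p-values may be too small. Sequencing depth is left open, since r = -0.326 to the replication score (permutation p = 0.29, n = 12) decides neither way, nor does the value centered by site (-0.181, exact p = 0.637). Without greater curvature 2 the centered value for depth turned to 0.322. Differences in tumor stage were not tested.

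Other splits of the samples were counted for each edgeR count. For all tumors against normal 1 of 100 splits, the real one, gave as many genes (5000 in a fit of 2 groups), a share under 0.05. These splits are a sample of those possible and treat the samples as independent, so the rank argues against chance without excluding it. The highest other split, with no normal in its small group, called 3826, which points to a structure among the tumors. It had 6828 genes at an unadjusted p under 0.05, against 7345 for the real one. Splits of 3 against 3 samples are too few for a share under 0.05. There 1 of 10 splits gave as many genes for the antrum (902, highest other 0), the greater curvature (4, highest other 3), the lesser curvature (5289, highest other 1) and the corpus (301, highest other 0), and 10 of 10 did for the greater against the lesser curvature (0 and 0). Any split gives at least 0 genes, so where the real count was 0 the splits test nothing: 60 of 60 among the 4 sites (highest other 1), for the antrum (highest other 3), the greater curvature (highest other 1) and the corpus (highest other 2607) against the other sites. For the lesser curvature 4 of 60 splits gave as many genes (1, highest other 2417), so chance is not excluded. The 2417 and 2607 genes came from 1 and the same split, which again points to a structure of the samples. By genes at an unadjusted p under 0.05, a count taken after the results were seen, 18 of 60 splits gave as many among the 4 sites (947, highest other 5176), 37 for the antrum (369, highest other 5700), 31 for the greater curvature (365, highest other 6054), 9 for the lesser curvature (1763, highest other 6134) and 14 for the corpus (1218, highest other 6525), so chance is not excluded for these.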

How the results depend on the processing

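Leaving out greater curvature 2 and corpus 1 together, and the overlap between sites under other settings, were chosen after the data were seen. Counts of genes moved by over 1.5 times without 3 of the 15 libraries for all tumors and for the lesser curvature against normal, 6 for the antrum, 10 for the greater curvature and 12 for the corpus. With DESeq2 size factors each count of genes stayed within 1.5 times. The cause was not tested unless given. A test above a 1.5-fold change, stricter by construction, left 1525 genes for all tumors, 448 for the antrum, 219 for the greater curvature, 1752 for the lesser curvature and 12 for the corpus. DESeq2 gave 4439 (antrum), 3800 (greater curvature), 2192 (corpus), 165 among the 4 sites, 68, 26, 244 and 63 (antrum, greater curvature, lesser curvature and corpus against the other sites), 83 between the curvatures and an overlap of 4713. No low-count filter, with more genes tested, gave 964 (greater curvature) and 331 (corpus). Compared groups only, with fewer samples, gave 902 (antrum), 4 (greater curvature), 301 (corpus), 12 among the sites, 117 (lesser curvature against the others), an overlap of 931 and 19 named genes. In comparisons between sites that fit held no normals. Limma on the TPM table gave 4047 (antrum), 3153 (greater curvature), 3 among the sites, 10 (lesser curvature against the others), 5 between the curvatures, an overlap of 4226, and reversed values of 0.0213 for Rrm2b and 0.0697 for Aldoa. Both values lie near 0, and the TPM table places the median gene 0.51 higher for all tumors against normal. Most of these 2 reversals is thus a shift of scale. The replicate block gave 1 (antrum against the others), 26 (lesser curvature against the others) and 1 between the curvatures, kept the other counts of genes within 1.5 times, and gained 20 list calls, such as adipocyte markers for all tumors (adjusted p = 0.0452), and lost 1. Of calls of single genes it lost 27 and gained 15. In the check of the block, 17 of 30 pairs of the same number correlated above 0.1 (range -0.566 to 0.693) and 10 of 15 libraries correlated best with their own number. All 3 pairs were above 0.1 for normal with antrum, normal with lesser curvature, antrum with lesser curvature and greater with lesser curvature. Pairs with a corpus tumor lay at 0.0178 or lower, except greater curvature 3 with corpus 3 (0.417). Among the other groups only normal 3 (0.0881) and antrum 3 (-0.177) with greater curvature 3 lay under 0.1. Samples of the same number outside the corpus thus tended to shift together, though no label says what a number stands for. Since not every pair of the 30 was above 0.1, the block was left out of the fit, and pairing outside the corpus stays open. Without greater curvature 2 and corpus 1 the counts were 3598 (antrum), 4430 (greater curvature), 1972 (corpus), 0 (lesser curvature against the others) and an overlap of 4496. With an estimated correlation 0 of 135 list calls by camera were left.

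Leaving out 1 library gave 2587 to 6900 genes for all tumors, 387 to 3297 (antrum), 1 to 4173 (greater curvature), 2159 to 6403 (lesser curvature) and 0 to 1218 (corpus). It gave 0 to 16 among the sites, 0 to 1 for the antrum, greater curvature and corpus against the others, 0 to 144 for the lesser curvature against the others, 0 to 0 between the curvatures, an overlap of 348 to 4248, 102 to 153 list calls and 31 to 62 named genes. Without normal 2 the squamous list reversed for all tumors (adjusted p = 0.000481) and the greater curvature (adjusted p = 0.0396), as did the values of Lor (0.37), Krt10 (1.59), Krt1 (1.89) and Krt4 (3.81). Over the fits with 1 library left out the adjusted p of the list ran from 0.000481 to 0.895 and 0.013 to 0.585, and the lowest values of these genes were -9.27, -8.12, -9.51 and -7.57. Over all fits with libraries left out, calls of single genes were lost 652 times and gained 66 times. Depth bounds a group at 0 only at its 3-count floor, 0.0565 CPM for the greater and 0.0597 CPM for the lesser curvature tumors.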

Other observations

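The tests of relations between scores in this part were chosen after the results were seen.

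Antigen presentation genes ran with pan-epithelial genes across the tumors and against neuroendocrine genes. Over the 12 tumors the pan-epithelial score rose with the antigen presentation score (Pearson r = 0.782, permutation p = 0.00107, adjusted p = 0.00375, n = 12, Spearman 0.776, and 0.546 without antrum 1 and lesser curvature 1). It rose with the interferon score too (r = 0.782, permutation p = 0.00039, adjusted p = 0.00273, Spearman 0.825, and 0.637 without the same libraries). The neuroendocrine score fell as the antigen presentation score rose (r = -0.676, permutation p = 0.0114, adjusted p = 0.0199, Spearman -0.762, and -0.609 without greater curvature 2 and corpus 1). H2-K1, a class I antigen-presenting molecule, had 145, 719 and 212 CPM in the lesser curvature tumors and 2162, 1122 and 1078 CPM in the corpus tumors. With scores centered on their site means r was 0.847 for pan-epithelial and interferon (exact p = 0.00231, adjusted p = 0.0054, n = 12) and -0.675 for neuroendocrine and antigen presentation (exact p = 0.000772, the smallest these orders can give, adjusted p = 0.0054). For pan-epithelial and antigen presentation r was 0.791, which missed the threshold (exact p = 0.0309, adjusted p = 0.054). The tumors lowest in antigen presentation score, antrum 1 (-2.59) and lesser curvature 1 (-3.32), were also lowest in chief cell score (-6.77 and -10.96). Corpus 1, the highest (1.67), had a chief cell score of -0.27, near that of the normals. Whether these relations follow the share of gastric mucosa in each sample was not tested.

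Cxcl5 and the neutrophil score were higher in the same tumors (r = 0.623, permutation p = 0.0261, adjusted p = 0.0365, n = 12), but the Spearman value of 0.552 had a permutation p of 0.0671, and without antrum 1 and greater curvature 2 the Pearson r was 0.483. For the macrophage score r was 0.526 (permutation p = 0.0767, n = 12), and 0.277 without those libraries. Centered by site, r was 0.555 for the neutrophil score (exact p = 0.188, n = 12) and 0.292 for the macrophage score (exact p = 0.494, n = 12), so neither relation was found within sites.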
